A study of Solanum lycopersicum with 24 samples.

How the data were processed

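RNA was sequenced from epicarp and mesocarp of tomato fruit of the genotype MT-Aft/atv/hp2, in 8 groups of 3 libraries: each tissue in light-grown control and in fruit covered from flowering for 30 d and then lit for 0 d, 2 d or 5 d. Per the labels' protocols, total RNA was extracted with a mirVana kit and 24 cDNA libraries were read as 150-base pairs on a NovaSeq 6000. The labels name Trimmomatic 0.39, featureCounts and DESeq2 as the authors' tools. The aligner and the use of strand in counting are not given in the sources used here, so reads in the part that overlapping genes share are treated as uncertain.

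The deposited count table holds whole read counts per gene, made by the authors with featureCounts and not normalized, for 34688 genes with positions on build SL4.0. Each gene is 1 interval from its start to its end, introns included, since the listed length equals that interval in all 34688 genes. The deposited TPM table holds TPM values made by the authors for 34689 genes; how these were computed is not given in the sources used here. The gene present only in the TPM table is F3'5'H, so its values and tests are on the TPM scale. The same column name, mesocarp at 2 d replicate 3, heads a pair of columns in the count table, and no column is named for mesocarp at 5 d replicate 3. These 2 columns were not used. Reads of both libraries were recovered from their TPM columns as TPM times gene length, divided by the step that makes all values whole. All genes (100.0%) came out whole within 0.01. The same recovery gave the deposited counts in every gene for the other 22 libraries. In these libraries the TPM values are thus the same reads, divided by the interval length and scaled per library. Tests on TPM are a rescaling of these reads and no separate count of them. Levels, folds and tests that involve mesocarp at 2 d or 5 d rest in part on these 2 recovered libraries. Other columns were matched to samples by name.

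Assigned reads ran from 18402751 to 23197867 per library, so 0 reads bounds a gene at 3 reads, or 0.129 to 0.163 CPM, by counting error alone. Between replicates the spread was at least 15.2 times that of counting error (chi-square over degrees of freedom), so replicates, and not depth, set the precision of the folds. Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM scaling, the filterByExpr filter by group (19620 genes kept), 1 model with a mean for each of the 8 groups, quasi-likelihood fits with robust estimation, and Benjamini-Hochberg adjustment within each contrast at 0.05. The common dispersion was 0.119. The 17 contrasts are the 10 between conditions within a tissue, the 4 between tissues within a condition and 3 interactions (epicarp effect minus mesocarp effect). Folds are first group minus second on the log2 scale. Their standard error is the fold divided by the square root of the F statistic. F3'5'H was tested with limma 3.58.1 (trend) on log2(TPM + 1). Principal components used log2 CPM with a prior count of 2. Files were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.

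Gene names come from the deposited descriptions and from symbols fixed by identifier before the data were examined, and 3801 genes are described only as unknown protein. Of 25 fixed lists, 14 were written as identifiers: early phenylpropanoid, anthocyanin biosynthesis, flavonol branch, anthocyanin regulators, light signalling, photoprotection and ascorbate, carotenoid pathway, chlorophyll and chloroplast, photosynthesis proteins, ripening, epidermis and cuticle, sugar and starch, glycoalkaloid pathway, and clock. The other 11 were drawn by words in the descriptions: photosystem, cytosolic ribosomal, heat shock, seed, histones and cell division, cell wall loosening, auxin response, vascular, wound and proteinase inhibitors, pathogenesis-related, and cutin and wax. Of 197 fixed identifiers, 178 were tested, 10 had too few reads, 3 were left out because the description names another family, and 6 matched no gene. Lists of at least 3 tested genes were tested with camera on voom values with a preset correlation of 0.01, adjusted over the lists of a contrast. Beside its p stand the lowest and highest of 3 alternatives: an estimated correlation, the replicate block, and fry. Camera compares a list with the other genes, whereas fry asks whether the list changed at all. Wherever camera passed, the highest came from the estimated correlation and the lowest from the block or fry. Counts of list members use the adjustment over all genes, with the count adjusted over the list alone beside it.

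Genes are named by a rule fixed before the data were examined. Members of the first 5 lists above may be named in any contrast. From another list up to 4 genes with the largest change past the threshold may be named, or the 2 with the smallest p where none passed. Outside the lists, the 5 highest and 5 lowest changes past the threshold may be named, with at least 10 CPM and no overlap between the libraries of the groups. The genes shown per library at 0 d (CD1, GPAT6, SUS1, LHY, PG2a, E8, NOR, ACS2) and the 11S globulin gene were chosen after their values were seen.

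Replicate numbers are shared by all groups, and whether they pair the samples was checked before calls were compared. Deviations from the group means correlated between epicarp and mesocarp of the same number by 0.39 to 0.64 at 0 d, 0.12 to 0.17 at 2 d and 0.19 to 0.30 at 5 d, against at most -0.11, -0.02 and -0.02 for other numbers. In control these were 0.21, 0.05 and 0.05, and between conditions of 1 tissue no pair of conditions had all of its same-number correlations above 0.1. The nearest was epicarp at 5 d with 2 d (0.13, 0.06 and 0.14, each the best match of its library). The pairing at 0 d, 2 d and 5 d thus comes from the data and not from the labels.

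The alternatives tried were DESeq2 1.42.0, RLE scaling, no low-count filter, a stricter filter (1 CPM in 3 libraries), a model of only the groups compared, the replicate number as a block, a minimum fold of 2 (log2 of 1), limma on log2(TPM + 1), on log2(TPM + 0.1) and on log2(TPM + 1) without a filter, and each library left out in turn. Another pair was added after the data were seen: without the 0 d libraries numbered 3, and without the 2 recovered libraries. The steps were tested on simulated data with 100 changed genes per fold. For epicarp at 2 d against 0 d, edgeR recovered 40% of genes changed 2-fold and 82% of those changed 4-fold, with 4 unchanged genes called among 19322. DESeq2 recovered 50% and 89% with 31 called, and limma on TPM 40% and 84% with 4 called among 18584. For an interaction edgeR recovered 10% and 64% with 6 called. A changed list reached a camera p of 7.1e-59 (estimated correlation 1.29e-10, fry 5.93e-14), and 0 of 24 unchanged lists were called by any of these. The simulated genes varied independently of each other, with the same spread in all groups. The simulation thus lacks list genes that vary together and the wider spread at 0 d. It cannot show how many false calls these cause in the real data.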

Results

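RNA sequencing was used to follow gene expression in the fruit of a purple tomato (Solanum lycopersicum, genotype MT-Aft/atv/hp2) that had developed in light or in darkness. Anthocyanins are the purple flavonoid pigments of this fruit. The genotype joins an allele that activates a pigment-promoting MYB gene (Aft), the loss of a MYB repressor (atv) and a mutation that heightens the response to light (hp2). The stated purpose of the study was to learn how anthocyanin accumulation is regulated in the outer tissues of the fruit. Control fruits grew in light for 30 d. Other flowers were wrapped in aluminium foil when they opened and stayed wrapped for 30 d, after which the fruits were collected at once (0 d) or after 2 d or 5 d in light. Darkness came only with the foil, so effects below called those of darkness cannot be told apart from those of the cover. Likewise, effects called those of light cannot be told apart from those of removing the cover. Epicarp, the skin of the fruit, and mesocarp, the flesh beneath it, were collected separately. Each of the 8 groups held 3 libraries, which makes 24 libraries in all.

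The total number of reads assigned to genes lay between 18402751 and 23197867 per library. In epicarp it spanned 18618384 to 21853831 in control, 18412051 to 20940821 at 0 d, 20568018 to 21871092 at 2 d and 20130065 to 21128384 at 5 d. In mesocarp it spanned 18465849 to 21355008 in control, 19526720 to 23158324 at 0 d, 18402751 to 21904682 at 2 d and 18925789 to 23197867 at 5 d. A gene with no read in a library may hold up to 3 reads by counting error alone, which is 0.129 to 0.163 CPM (the read count scaled to the library's total). Between 18722 and 20625 genes had at least 1 read per library, and the 10 most abundant genes took 6.83% to 12.39% of the reads. Reads are not independent molecules, so these limits cover counting error only. The labels do not say that the replicates came from separate plants or fruits, so the p-values measure only the spread between these samples. Levels below are given as mean CPM ± SD (n = 3). Gene positions refer to the tomato genome build SL4.0. Changes are given on the log2 scale ± standard error with edgeR's adjusted p. Unless stated otherwise, for a change past the threshold the 3 libraries of 1 group all lay above or all lay below the 3 of the other. Chance gives this separation to 10% of genes.

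Tissue was the main axis of variation across the 24 libraries. The first principal component held 36.9% of the variance and put epicarp at scores of -28.3 to -111 and mesocarp at 63.6 to 112.6. The second component held 21.9% and put all 12 libraries lit for 2 d or 5 d at -6.4 to -81.9, the controls at 53.1 to 63.1 and the 0 d libraries at 18.3 to 124.7. The third component held 12.1% and spread the 0 d libraries apart. Epicarp replicates 1, 2 and 3 scored 13.6, -72.2 and -148.7 on it, and mesocarp replicates 1, 2 and 3 scored 39.7, -33.3 and -116.5. Correlations of log CPM between replicates were 0.8712 to 0.9369 at 0 d in epicarp and 0.8744 to 0.9337 in mesocarp, against 0.9517 to 0.9847 in the other groups.

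**Figure D1:**
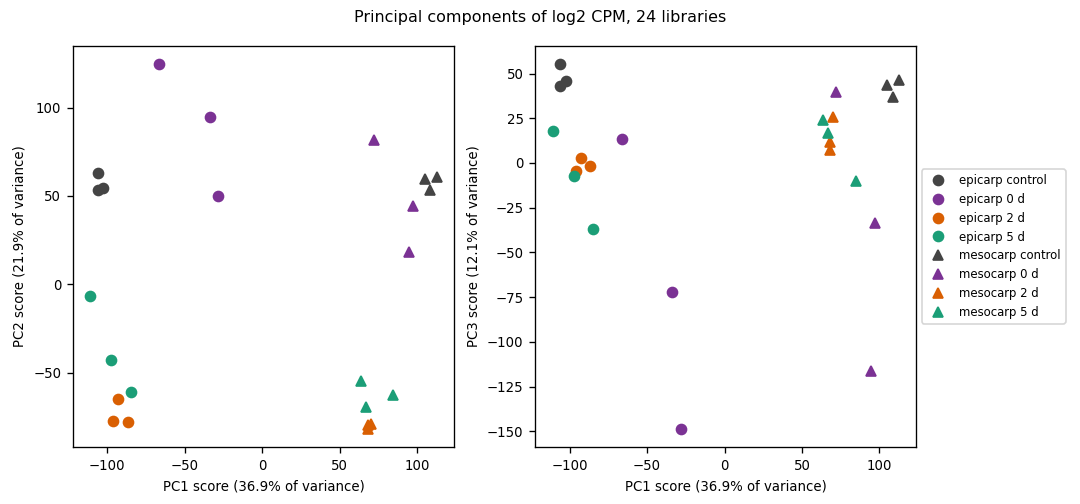
Scores of the 24 libraries on principal component 1 (36.9% of variance) against components 2 (21.9%) and 3 (12.1%) of log2 CPM; colours are the light conditions, circles epicarp and triangles mesocarp. Epicarp lies at negative and mesocarp at positive scores on component 1, and the 0 d libraries span 39.7 to -148.7 on component 3.

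The 0 d replicates differed from each other in genes of cuticle formation and ripening, and in 1 gene each of sugar use (SUS1) and the clock (LHY). These genes were chosen after their values were seen, and the sugar and clock lists were not tested for such a difference. CD1 (Solyc11g006250.2), which encodes the enzyme that polymerises cutin, stood at 5720 CPM in epicarp replicate 1, 78.05 CPM in replicate 2 and 0.26 CPM in replicate 3. GPAT6 (Solyc09g014350.3), an acyltransferase of cutin synthesis, stood at 2376, 37.3 and 0.37 CPM in these libraries. PG2a (Solyc10g080210.2), the pectin-cutting polygalacturonase of ripe fruit, had 0 reads in replicate 1 and stood at 22 CPM in replicate 2 and 590.5 CPM in replicate 3. NOR (Solyc10g006880.3), a NAC factor that drives ripening, stood at 0.05, 3.04 and 188.6 CPM, and E8 (Solyc09g089580.4), an ethylene-responsive gene of ripening fruit, stood at 96.6, 162.9 and 2054 CPM. The anthocyanin gene DFR lay between 0.31 and 1.36 CPM in all 6 libraries at 0 d. In several contrasts with 0 d, an estimate made only from the groups compared gave far fewer genes than the estimate shared by all 24 libraries. The shared estimate may understate the spread at 0 d, so p-values of contrasts with 0 d may be too low.

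**Figure D2:**
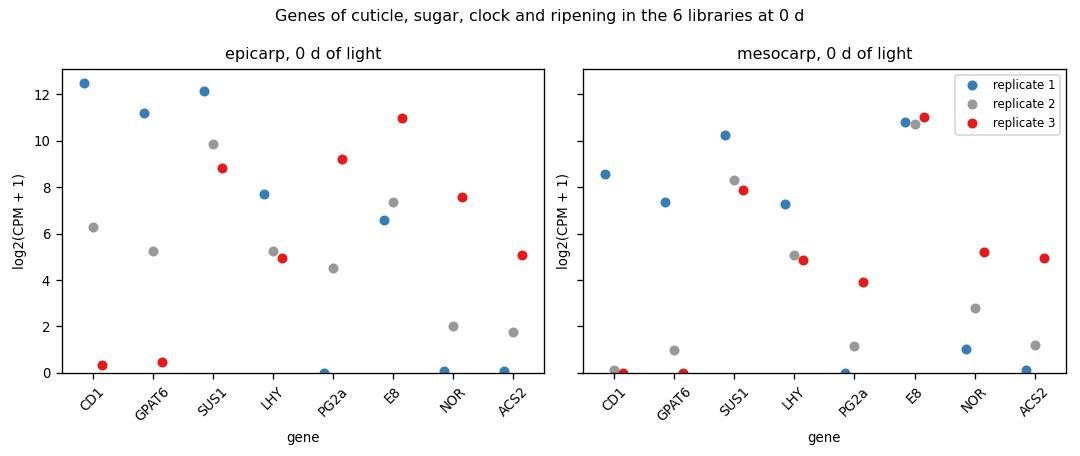
Level of 8 genes, as log2(CPM + 1), in the 3 epicarp (left) and 3 mesocarp (right) libraries at 0 d; each point is 1 library and the colour is its replicate number. CD1 ran from 0.26 to 5720 CPM and NOR from 0.05 to 188.6 CPM across the epicarp libraries.

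Epicarp and mesocarp of light-grown fruit were compared to learn how the skin differs from the flesh when the fruit has not been shaded. The skin carried more transcripts of the pigment pathway and of the cuticle. Across the 19620 genes tested, 2595 were higher in epicarp and 2664 were lower (5259 in all, 26.8%). All 15 tested genes of anthocyanin biosynthesis were higher in epicarp, and the same 15 were counted when p was adjusted over the list alone (camera adjusted p 1.31e-23, alternatives 9.97e-21 to 0.0315). DFR (Solyc02g085020.4, chromosome 2, 46065285 to 46067689), the reductase that commits the pathway to anthocyanins, stood at 1470 ± 135 CPM in epicarp and 2.046 ± 0.276 CPM in mesocarp, a log2 difference of 9.49 ± 0.40 (adjusted p 1.27e-11). Its annotated interval shares 195 bases with that of a neighbouring gene, so some of its reads may belong to either. ANS (Solyc08g080040.4, chromosome 8, 61491075 to 61492935), the oxygenase that forms the coloured anthocyanidin, differed by 7.59 ± 0.47 (2.68e-09) and shares 276 bases with a neighbour. CHS1 (Solyc09g091510.3, chromosome 9, 66873902 to 66876060), the chalcone synthase at the entry to flavonoids, stood at 1319 ± 214 CPM against 0.8163 CPM (10.64 ± 0.71, 5.86e-09). The glucosyltransferase gene 5GT (Solyc12g098590.3) differed by 9.76 ± 0.45 (3.5e-11). F3'5'H (Solyc11g066580.3), whose product adds the hydroxyl groups of the blue-purple delphinidin pigments, appeared only in the TPM table, whose values are scaled to gene length and library total. It stood at 1011 ± 72.6 TPM in epicarp and 0.6933 ± 0.207 TPM in mesocarp (limma on log2(TPM + 1), 9.23, adjusted p 3e-14).

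The regulators of the pathway were also higher in the skin of light-grown fruit. In this list 9 of 12 tested genes were higher in epicarp, also when adjusted over the list alone (camera 1.89e-05, alternatives 5.52e-07 to 0.0457). AN1 (Solyc09g065100.3, chromosome 9, 59048134 to 59055605), the bHLH partner of the MYB activators, differed by 9.10 ± 0.57 (3.12e-09). AN11 (Solyc03g097340.1, chromosome 3, 54221599 to 54222627), the WD40 partner in the same complex, differed by 1.37 ± 0.18 (2.05e-05). WRKY44 (Solyc10g084380.1), a WRKY factor linked to pigmentation, differed by 6.95 ± 0.91 (2.01e-05). MYB-ATV (Solyc07g052490.4), the repressor whose function the atv allele removes, stood at 15.36 ± 1.80 CPM in epicarp and 0.2021 ± 0.0412 CPM in mesocarp. AN2-like (Solyc10g086290.3, chromosome 10, 64316975 to 64318348), the MYB activator, stood at 793.9 ± 127 CPM in epicarp and already at 135.6 ± 31.2 CPM in mesocarp. Its difference of 2.55 ± 0.75 (0.0163) did not pass without mesocarp control replicate 1 (0.0584) or 2 (0.054). AN2 (Solyc10g086250.2), another MYB activator, stayed at or below 1.129 CPM in every group mean, and ANT1 (Solyc10g086260.3) had no reads in any library. Early phenylpropanoid genes feed the pathway, and 7 of 11 were higher in epicarp (8 adjusted over the list alone; camera 7.58e-07, alternatives 3.71e-07 to 0.0457). PAL_09g007920 (Solyc09g007920.4, chromosome 9, 1455211 to 1458871), a phenylalanine ammonia-lyase, differed by 4.33 ± 0.48 (2.87e-06).

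Both genes of the flavonol branch were higher in the skin of light-grown fruit. FLS (Solyc11g013110.2), the flavonol synthase, differed by 3.33 ± 0.66 (0.00107), and MYB12 (Solyc01g079620.5), its MYB activator, by 2.04 ± 0.43 (0.00165). Among cuticle genes, 10 of 11 were higher in epicarp (11 adjusted over the list alone; camera 8.54e-08, alternatives 4.64e-12 to 0.0468). CER3 (Solyc03g117800.4), which acts in wax alkane synthesis, stood at 208.1 ± 85.3 CPM in epicarp and 0.4298 CPM in mesocarp (8.93 ± 0.75, 1.68e-07). In the other direction, 12 of 29 vascular genes were lower in epicarp, as when adjusted over the list alone (camera 0.000534, alternatives 0.000149 to 0.386). A sieve element occlusion gene (Solyc03g111810.2) had no reads in the epicarp controls and stood at 34.5 ± 13.7 CPM in mesocarp. PHYB2 (Solyc05g053410.5), a phytochrome that senses red light, was lower in epicarp by -1.55 ± 0.25 (0.000131). E8 was lower in epicarp by -6.30 ± 1.02 (0.000175).

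**Figure D3:**
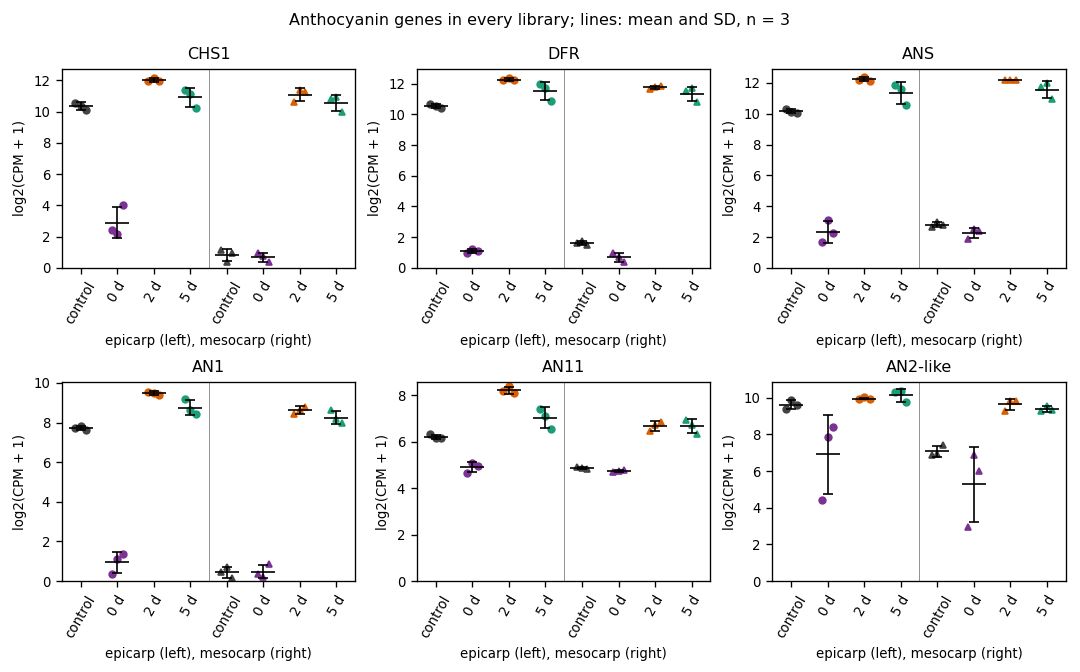
Level of 6 anthocyanin genes as log2(CPM + 1) in every library, by tissue and light condition; black lines are the mean and SD of 3 libraries. DFR stood at 1470 CPM in epicarp control, 1.147 CPM in epicarp at 0 d, 4922 CPM in epicarp at 2 d, 2.046 CPM in mesocarp control and 3479 CPM in mesocarp at 2 d.

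Fruit kept dark from flowering was compared with light-grown fruit in epicarp to learn what the skin expresses when light has never reached it. The pigment pathway was lower. Of 19620 genes, 1973 were higher and 1782 lower at 0 d than in control (3755 in all, 19.1%). This balance turned whenever 1 library was left out, with 40.6% to 48.3% of the calls higher. It also turned with a minimum fold of 2 (778 higher and 1051 lower). The total was 2210 without 0 d replicate 2, 2266 without control replicate 1 and 2372 without control replicate 2. It was 898 when the spread was estimated only from the groups compared. In anthocyanin biosynthesis, 14 of 15 genes fell (15 adjusted over the list alone; camera 7.93e-27, alternatives 2.55e-27 to 0.0181). DFR was at 1.147 ± 0.195 CPM at 0 d, a fall from control of -10.32 ± 0.42 (8.93e-12). The change was -11.16 ± 0.48 for 5GT (9.65e-12), -8.02 ± 0.48 for ANS (2.27e-09) and -7.40 ± 0.61 for CHS1 (1.99e-07). GST (Solyc02g081340.3), the glutathione transferase that carries anthocyanins to the vacuole, changed by -10.93 ± 0.54 (9.82e-11). F3'5'H went from 1011 ± 72.6 to 0.4946 ± 0.182 TPM (-9.41, 2.53e-14). A pair of enzymes kept more of their transcripts. F3H (Solyc02g083860.3, chromosome 2, 45122808 to 45124818), the flavanone hydroxylase, was still at 362.8 ± 105 CPM and changed by -2.42 ± 0.54 (0.00444). A3GT (Solyc10g083440.3), the glucosyltransferase that acts on the anthocyanidin, was at 332.3 ± 24.7 CPM and changed by -1.72 ± 0.47 (0.0156), which did not pass without 0 d replicate 2 (0.0597).

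The regulators and the light-signalling genes of dark-grown epicarp were examined for changes that go with the low pigment genes. In the regulator list, 5 of 12 genes fell (7 adjusted over the list alone; camera 2.9e-05, alternatives 6.1e-06 to 0.0628). AN1 fell to 1.018 ± 0.68 CPM (-7.69 ± 0.53, 1.68e-08), WRKY44 changed by -5.29 ± 0.81 (0.000243) and AN11 by -1.34 ± 0.18 (7.02e-05). The activator AN2-like was not past the threshold (-2.0 ± 0.73, 0.0637), and it passed without 0 d replicate 3 (-2.68, 0.044). It also passed with the replicate number as a block, a pairing that was not found between these conditions. Its 0 d libraries stood at 20.48, 232.69 and 343.85 CPM. PAL_09g007920 changed by -3.35 ± 0.46 (7.73e-05). The list of early phenylpropanoid genes had 6 of 11 lower (9 adjusted over the list alone, and 3 over all genes without 0 d replicate 2; camera 2.85e-07, alternatives 7.72e-07 to 0.0508). CRY3 (Solyc08g074270.4), a cryptochrome-family blue-light receptor, changed by -1.92 ± 0.40 (0.00303). HY5 (Solyc08g061130.3), a bZIP factor that promotes light responses, stood at 13.98, 97.91 and 178.2 CPM at 0 d against 23.16 ± 6.05 CPM in control, so its libraries overlapped.

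Some chloroplast genes of dark-grown epicarp were lower than in light-grown skin. Among photosynthesis proteins, 15 of 26 fell (18 adjusted over the list alone; camera 1.18e-08, alternatives 5.62e-08 to 0.448). This count was 8 without 0 d replicate 2, 9 without control replicate 1 and 1 when only the groups compared set the spread. GLK2 (Solyc10g008160.3), the factor that promotes chloroplast development in fruit, changed by -3.75 ± 0.54 (0.000146). VDE (Solyc04g050930.3), which converts violaxanthin to zeaxanthin under strong light, changed by -3.64 ± 0.32 (3.83e-07). FeSOD (Solyc06g048410.4), a chloroplast superoxide dismutase, changed by -2.20 ± 0.31 (8.95e-05), and ZDS (Solyc01g097810.3), a carotene desaturase, by -1.05 ± 0.16 (0.000192). GAME4 (Solyc12g006460.2), a cytochrome P450 of glycoalkaloid synthesis, changed by -1.82 ± 0.25 (8.65e-05). A glycolate oxidase gene (Solyc10g007600.3), whose product acts in photorespiration, rose from 1.10 to 140 ± 103 CPM (6.95 ± 1.00, 0.000141). A chitinase gene (Solyc11g072830.1), of a family that degrades fungal walls, fell from 40.8 ± 2.39 to 0.355 CPM (-6.83 ± 0.50, 3.47e-08). Of 18 ripening genes 8 rose (9 adjusted over the list alone; camera 0.156), a count that was 2 without 0 d replicate 3 or without control replicate 1, 2 or 3. With only the groups compared edgeR called 0 of them (4 at an unadjusted p under 0.05), against 8 by DESeq2 and 3 by limma on TPM.

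The same comparison in mesocarp asked what differed in the flesh of covered, dark-grown fruit. Its pigment genes were already low in light-grown fruit. Here 471 genes were higher and 373 lower (844 in all, 4.3%). The total was 1938 without 0 d replicate 1, 459 without 0 d replicate 3, and 501, 408 and 419 without control replicates 1, 2 and 3. By limma on log2(TPM + 1) it was 1419, of which 20.5% were higher against 55.8% here, and by DESeq2 1742. With only the groups compared it was 6, and none of the mesocarp calls named in this paragraph held in that fit. DFR went from 2.046 ± 0.276 to 0.6422 ± 0.344 CPM (-1.67 ± 0.34, 0.0101). VDE changed by -1.58 ± 0.29 (0.00616), FeSOD by -1.74 ± 0.30 (0.00426), GAME4 by -1.60 ± 0.25 (0.00232) and PHYB2 by -1.26 ± 0.25 (0.00779). CAB3A (Solyc03g005760.1), a chlorophyll-binding antenna protein, rose from 173.2 ± 23.4 to 652.3 ± 330 CPM (1.91 ± 0.38, 0.00913). Of 201 cytosolic ribosomal protein genes, 32 rose (61 adjusted over the list alone; camera 3.85e-18, alternatives 2.84e-18 to 0.643), a count that was 16 without control replicate 2 and 14 without control replicate 3. Cuticle genes took 0.0346% ± 0.0471 of the reads at 0 d (0.0046% to 0.0889%) against 0.0053% ± 0.000186 in control, and CD1 stood at 376.97 CPM in 0 d replicate 1 and at most 0.08 CPM in replicates 2 and 3. A seed storage gene, 11S globulin (Solyc09g072560.5), stood at 55.9 ± 11.5 CPM in mesocarp control and had no reads at 0 d.

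Whether darkness acted differently in skin and flesh was tested as the epicarp effect minus the mesocarp effect. The skin lost far more of its pigment transcripts, of which the flesh had few to lose. F3'5'H, for example, stood at 1011 TPM in epicarp control and 0.6933 TPM in mesocarp control. Pigment genes this low in light-grown flesh could hardly fall there. Their differences therefore do not show that the flesh responds less to darkness. In this interaction 146 genes were higher and 357 lower (503 in all, 2.6%). The total was 1348 without epicarp 0 d replicate 1, 307 without epicarp 0 d replicate 2, 318 and 289 without epicarp control replicates 1 and 3, and 322 without mesocarp control replicate 3. It was 58 with only the groups compared, 1187 by DESeq2 and 1451 with the samples of a number paired as a block, a pairing seen at 0 d and not in control. On TPM 56.9% of the calls were higher, against 29.0% here. In anthocyanin biosynthesis, 10 of 15 genes had a lower epicarp effect (13 adjusted over the list alone; camera 6.97e-22, alternatives 7.99e-24 to 0.0442). The difference was -8.65 ± 0.50 for DFR (6.95e-09), -7.39 ± 0.57 for ANS (2.39e-07), -9.33 ± 0.56 for 5GT (8.43e-09) and -9.89 ± 0.66 for GST (2.44e-08). It was -7.83 ± 0.80 for AN1 (1.47e-05), -1.20 ± 0.25 for AN11 (0.0159), -5.07 ± 0.77 for the chitinase gene Solyc11g072830.1 (0.0015) and -9.03 for F3'5'H on the TPM scale (2.52e-11). Photosynthesis proteins had 15 of 26 genes with a lower epicarp effect (22 adjusted over the list alone; camera 7.11e-21, alternatives 4.92e-21 to 0.151), a count that was 8 without mesocarp control replicate 3. With only the groups compared edgeR called 0 of them (21 at an unadjusted p under 0.05), against 21 by DESeq2 and 18 by limma on TPM. CAB3B (Solyc03g005770.4), another antenna protein, differed by -6.03 ± 1.08 (0.00542) and PHYB2 by 1.70 ± 0.34 (0.0128), and neither passed with only the groups compared. Across genes, which are not independent replicates, the effects of darkness in the tissues had a Pearson correlation of 0.40 and a Spearman correlation of 0.38.

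Dark-grown fruit lit for 2 d was compared with fruit at 0 d to learn how the skin responds when light first reaches it. Transcripts of the anthocyanin pathway rose, as did those of its regulators. These fruits were also 2 d older and no longer covered, so age, light and removal of the cover cannot be separated. In epicarp 3462 genes were higher and 3737 lower (7199 in all, 36.7%). This balance turned when any library but 0 d replicate 3 was left out, with 51.2% to 54.5% of the calls higher. It also turned with a minimum fold of 2 (2096 higher and 2017 lower). All 15 tested anthocyanin genes rose, also when adjusted over the list alone (camera 5.98e-21, alternatives 2.63e-21 to 0.0389). DFR rose to 4922 ± 295 CPM, a change of 12.06 ± 0.44 (1.31e-12). The changes were 12.45 ± 0.49 for 5GT (2.71e-12), 10.08 ± 0.52 for ANS (1.09e-10), 9.06 ± 0.65 for CHS1 (8.58e-09), 4.0 ± 0.58 for F3H (3.02e-05) and 2.94 ± 0.49 for A3GT (0.000133). F3'H (Solyc03g115220.5, chromosome 3, 59425127 to 59430606), the hydroxylase of the cyanidin and quercetin branches, rose by 4.63 ± 0.63 (1.67e-05). F3'5'H rose to 2208 ± 201 TPM (10.53, 2.3e-15). Of 11 early phenylpropanoid genes 10 rose, also when adjusted over the list alone (camera 4.81e-07, alternatives 1.98e-08 to 0.0389), with PAL_10g086180 (Solyc10g086180.2) up by 4.89 ± 0.62 (7.6e-06). FLS was at 816.4 ± 273 CPM at 0 d and 1268 CPM at 2 d and did not pass (0.63 ± 0.61, 0.443).

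In the skin after 2 d of light, 10 of 12 anthocyanin regulators rose, also when adjusted over the list alone (camera 3.5e-06, alternatives 1.06e-08 to 0.0389). AN1 rose to 714.8 ± 44.7 CPM (9.46 ± 0.56, 7.65e-10), WRKY44 to 313.4 ± 35.8 CPM (7.52 ± 0.88, 3.5e-06) and AN11 to 298 ± 31.0 CPM (3.36 ± 0.19, 5.79e-10). MYB-ATV (chromosome 7, 60912702 to 60913855) went from 0.2431 ± 0.21 to 194.9 ± 34.1 CPM. AN2-like rose by 2.32 ± 0.74 (0.0198), a call lost when only the groups compared set the spread. BBX24 (Solyc06g073180.3), a B-box factor of light signalling, rose by 1.37 ± 0.24 (0.000212), CRY1b (Solyc12g057040.2), a blue-light receptor, by 1.45 ± 0.26 (0.000214) and COP1-like (Solyc11g011980.3), related to a ligase that removes light-signalling factors, by 3.04 ± 0.58 (0.000441). PHYB2 fell by 1.74 ± 0.25 (2.66e-05). PRR5 (Solyc03g081240.3), a clock gene, changed by -3.99 ± 0.42 (8.46e-07).

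Chloroplast and stress genes of the skin also changed in the first 2 d of light. VDE rose by 4.90 ± 0.33 (3.53e-09) and GLK2 by 4.30 ± 0.55 (8.79e-06). POR_07g054210 (Solyc07g054210.3), a light-dependent enzyme of chlorophyll synthesis, rose by 1.89 ± 0.22 (2.9e-06), and the antenna gene CAB6A (Solyc05g056050.3) by 3.42 ± 0.62 (0.000287). Of 68 photosystem genes 50 rose and 2 fell (52 and 2 adjusted over the list alone; camera 3.77e-17, alternatives 6.63e-16 to 0.342). Of 56 heat shock genes 26 rose and 5 fell (29 and 6 adjusted over the list alone; camera 3.5e-06, alternatives 5.93e-06 to 0.388). A small chloroplast heat shock protein gene (Solyc03g082420.3) rose from 11.1 to 1110 ± 217 CPM (6.64 ± 1.18, 0.000251), and its interval shares 129 bases with a neighbour. SUS3 (Solyc07g042550.3), a sucrose synthase, rose by 1.35 ± 0.29 (0.0014), and GAME11 (Solyc07g043420.3), of glycoalkaloid synthesis, changed by -1.54 ± 0.23 (3.38e-05). A pectinesterase gene (Solyc01g098940.3) had no reads at 0 d and stood at 32.8 ± 9.84 CPM at 2 d. Of 18 ripening genes 10 fell, also when adjusted over the list alone (camera 0.119), a count that was 5 without 0 d replicate 3, and 3, 3 and 6 without 2 d replicates 1, 2 and 3.

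The flesh was compared at the same times to learn whether it responds to light as the skin does. The pigment pathway, low in the flesh of light-grown fruit, was expressed there after 2 d of light. Mesocarp had 2606 genes higher and 2113 lower at 2 d than at 0 d (4719 in all, 24.1%), and 2146 in all with only the groups compared. On TPM 36.3% of the calls were higher, against 55.2% here. All 15 tested anthocyanin genes rose, also when adjusted over the list alone (camera 1.09e-25, alternatives 6.37e-26 to 0.0198). DFR rose to 3479 ± 240 CPM (12.40 ± 0.45, 7.52e-13) and ANS to 4633 ± 49.1 CPM (10.22 ± 0.53, 1.32e-10). The changes were 12.48 ± 0.50 for 5GT (2.8e-12), 11.79 ± 0.74 for CHS1 (2.08e-09), 8.13 ± 0.70 for F3H (1.36e-07) and 7.18 ± 0.60 for A3GT (9.46e-08). F3'5'H rose to 815.8 ± 41.1 TPM (9.30, 2.23e-14), and F3'H changed by 4.30 ± 0.63 (6.5e-05) and reached 85.72 ± 29.5 CPM. PAL_09g007920 rose by 6.15 ± 0.53 (1.03e-07). AN1 rose to 398.2 ± 49.9 CPM (9.89 ± 0.58, 1.31e-09), AN2-like to 810 ± 160 CPM (3.71 ± 0.79, 0.00195) and AN11 to 101.8 ± 14.4 CPM (1.98 ± 0.18, 3.07e-07). MYB-ATV had no reads in mesocarp at 0 d and stood at 134.6 ± 55.2 CPM at 2 d.

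Genes outside the pigment pathway also changed in the flesh in the first 2 d of light. JAF13 (Solyc08g081140.4), a bHLH factor upstream of AN1, rose by 1.21 ± 0.16 (1.47e-05) and BBX24 by 1.90 ± 0.25 (1.63e-05). PIF1b (Solyc06g008030.3), a phytochrome-interacting factor, changed by -1.87 ± 0.35 (0.000755) and PRR5 by -2.22 ± 0.38 (0.0003). HY5 overlapped between the groups and did not pass (-0.95 ± 0.63, 0.301). GLK2 rose by 4.98 ± 0.53 (1.99e-06), VDE by 4.51 ± 0.32 (1.25e-08) and CHLH (Solyc04g015750.3), a subunit of the enzyme that inserts magnesium during chlorophyll synthesis, by 1.73 ± 0.34 (0.000879). The PsbS gene of photosystem II (Solyc06g060340.3), whose product helps to dissipate excess light, rose by 5.05 ± 0.82 (0.000192). Of 56 heat shock genes 34 rose and 2 fell (35 and 2 adjusted over the list alone; camera 1.33e-13, alternatives 6.86e-13 to 0.127). A heat shock gene (Solyc03g123540.3) rose by 5.19 ± 0.53 (1.02e-06). Of 201 ribosomal protein genes 94 fell (109 adjusted over the list alone; camera 1.11e-19, alternatives 6.16e-20 to 0.254), a count that was 49 without 0 d replicate 1 and 25 with only the groups compared. A proteinase inhibitor II gene (Solyc11g020960.2), of wound defence, changed by -4.90 ± 0.81 (0.000228).

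Whether the first light response differed between the tissues was tested as the epicarp change minus the mesocarp change. Enzymes that had stayed expressed in dark skin were among the genes that passed. In this interaction 131 genes were higher and 113 lower (244 in all, 1.2%). The total was 930 with the epicarp and mesocarp samples of a number paired as a block, 762 by DESeq2 and 47 with only the groups compared. By limma on log2(TPM + 1) it was 404, of which 74.8% were higher against 53.7% here. It was 490 without the 0 d libraries numbered 3 and 155 without both libraries with recovered reads. It was 469 without epicarp 0 d replicate 1, 438 without epicarp 0 d replicate 3, 158, 120 and 129 without epicarp 2 d replicates 1, 2 and 3, and 151 without mesocarp 2 d replicate 1. AN11 rose more in epicarp (1.38 ± 0.25, 0.00758), a call kept in every alternative. F3H changed less in epicarp (-4.13 ± 0.76, 0.00776), as did A3GT (-4.24 ± 0.68, 0.0029), PAL_09g007900 (Solyc09g007900.5; -2.82 ± 0.53, 0.00924) and a nitrate transporter gene (Solyc05g009500.3; -7.71 ± 1.40, 0.00758). These 4 calls were lost with only the groups compared. F3H and A3GT were already higher in epicarp than in mesocarp at 0 d. Their smaller changes therefore do not show a weaker light response of the skin. F3'5'H did not differ past the threshold (1.23, 0.139). Across genes, the changes in both tissues had a Pearson correlation of 0.65 and a Spearman correlation of 0.65. Genes that rose in both numbered 2033 against 459.8 if the tissues were independent, and genes that fell in both numbered 1466 against 402.5. Independence leaves out that epicarp and mesocarp 0 d libraries of the same number deviated together (0.39 to 0.64), which moves both effects alike, so neither these excesses nor the correlations of effects measure a shared response alone.

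**Figure D4:**
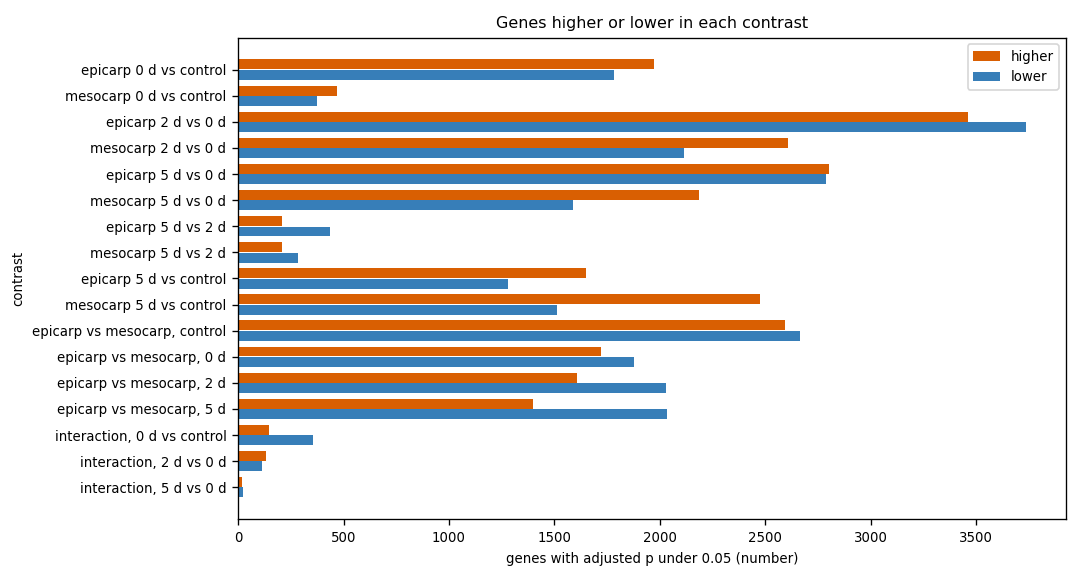
Number of genes with an edgeR adjusted p under 0.05 in each of the 17 contrasts, higher (orange) or lower (blue) in the first-named group; for an interaction, higher means a larger epicarp effect. The counts run from 17 higher and 21 lower in the interaction at 5 d to 3462 higher and 3737 lower in epicarp at 2 d.

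A longer exposure of 5 d was compared with 0 d to learn whether the response to light lasts. The pigment pathway stayed high in both tissues. The 5 d fruits were 5 d older than those at 0 d, and no longer covered. In epicarp 2803 genes were higher and 2787 lower (5590 in all, 28.5%), and 2790 in all with only the groups compared. In mesocarp 2186 were higher and 1587 lower (3773 in all, 19.2%). The mesocarp total was 2347 without 5 d replicate 2, 2473 without both libraries whose reads were recovered from TPM, and 802 with only the groups compared. On TPM 40.7% of the mesocarp calls were higher, against 57.9% here. All 15 tested anthocyanin genes rose in epicarp (camera 4.96e-24, alternatives 2.08e-24 to 0.0281) and in mesocarp (1.04e-27, alternatives 7.9e-28 to 0.0148), and all 15 did so when adjusted over the list alone. DFR was up by 11.37 ± 0.43 in epicarp (2.04e-12) and by 12.02 ± 0.44 in mesocarp (1.05e-12), and AN1 by 8.76 ± 0.55 (2.75e-09) and 9.53 ± 0.58 (2.07e-09). F3'5'H was up by 10.03 (5.65e-15) and 9.49 (1.55e-14). PAL_09g007920 reached 17970 ± 5600 CPM in epicarp (4.42 ± 0.48, 1.92e-06) and 16560 ± 5720 CPM in mesocarp (7.11 ± 0.55, 5.58e-08). AN11 rose by 2.21 ± 0.19 in epicarp (9.19e-08) and 1.99 ± 0.18 in mesocarp (5.42e-07).

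Genes outside the pigment pathway also differed between 5 d and 0 d. Of 68 photosystem genes 53 rose in epicarp (54 adjusted over the list alone; camera 1.59e-22, alternatives 8.19e-21 to 0.206) and 47 in mesocarp (50 over the list alone; camera 1.34e-16, alternatives 1.66e-15 to 0.249), where the count was 31 without 5 d replicate 3 and 11 with only the groups compared. GLK2 rose by 5.96 ± 0.58 in epicarp (6.41e-07) and by 4.21 ± 0.51 in mesocarp (1.59e-05). In epicarp CAB6A rose by 4.01 ± 0.63 (0.000101), HEMA_04g076870 (Solyc04g076870.4), which starts tetrapyrrole synthesis, by 1.76 ± 0.25 (2.91e-05), CER3 by 2.12 ± 0.52 (0.0047) and GAME4 by 1.05 ± 0.25 (0.00353), while PRR5 fell by 2.04 ± 0.38 (0.000497). In mesocarp ZEP (Solyc02g090890.4), which makes violaxanthin, rose by 1.41 ± 0.19 (3.31e-05) and CAB13 (Solyc07g022900.4) by 2.29 ± 0.56 (0.00714). A pectate lyase gene (Solyc05g014000.5), of cell wall softening, fell from 224 ± 227 to 11.7 ± 3.71 CPM in mesocarp (-4.26 ± 0.90, 0.00248). F3'H in mesocarp at 5 d stood at 4.38, 13.93 and 49.93 CPM, overlapped the 0 d libraries, and its change of 2.39 ± 0.59 (0.00733) became 1.07 (0.13) without 5 d replicate 3. The call was also lost with only the groups compared, without both recovered libraries, and by limma on log2(TPM + 1) without a filter. The interaction held 17 genes higher and 21 lower (38 in all, 0.2%), 258 in all with the paired block, 280 by DESeq2 and 1 with only the groups compared. By limma on log2(TPM + 1) it held 81, of which 58.0% were higher against 44.7% here, and by edgeR 109 without the 0 d libraries numbered 3 and 13 without both libraries with recovered reads. The total was 115 and 69 without epicarp 0 d replicates 1 and 3, 10 without epicarp 5 d replicate 1 or 2, 24 and 101 without mesocarp 0 d replicates 2 and 3, and 13, 14 and 20 without mesocarp 5 d replicates 1, 2 and 3. A3GT changed less in epicarp (-4.01 ± 0.67, 0.0191), a call lost without epicarp 5 d replicate 1 (0.0552) or 2 (0.0788), mesocarp 0 d replicate 2 (0.0608), or mesocarp 5 d replicate 1 (0.0572) or 2 (0.0585), and with only the groups compared. Across genes the changes at 5 d had a Pearson correlation of 0.64 and a Spearman correlation of 0.64.

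The light times were compared with each other to learn what changed between 2 d and 5 d. Heat shock genes were among those that fell. Epicarp had 208 genes higher and 434 lower at 5 d (642 in all, 3.3%). This total was 248, 242 and 313 without 2 d replicates 1, 2 and 3, 198 and 224 without 5 d replicates 2 and 3, 2406 with only the groups compared and 1348 by DESeq2. Mesocarp had 209 higher and 283 lower (492 in all, 2.5%). That total was 162 and 262 without 2 d replicates 1 and 3, 297, 173 and 272 without 5 d replicates 1, 2 and 3, 121 without both libraries with recovered reads and 1104 by DESeq2. In mesocarp more genes were higher than lower without 2 d replicate 2 (204 and 182) and without 5 d replicate 1 (159 and 138) or 2 (94 and 79). Of 56 heat shock genes 8 fell in epicarp (20 adjusted over the list alone; camera 6.76e-11, alternatives 1.88e-10 to 0.442) and 10 in mesocarp (18 over the list alone; camera 1.19e-14, alternatives 5.28e-14 to 0.5). The 8 became 4, 4 and 3 without epicarp 2 d replicates 1, 2 and 3 and 5, 3 and 3 without epicarp 5 d replicates 1, 2 and 3. The 10 became 2 and 5 without mesocarp 2 d replicates 1 and 3 and 4, 2 and 4 without mesocarp 5 d replicates 1, 2 and 3. Of 15 anthocyanin biosynthesis genes edgeR called 0 in epicarp (4 lower at an unadjusted p under 0.05, 0 called by DESeq2 or limma on TPM) and 0 in mesocarp (1 lower unadjusted, 1 called by DESeq2 and 1 by limma). DFR changed by -0.69 ± 0.28 in epicarp (0.185) and by -0.37 ± 0.28 in mesocarp (0.543). As a set the anthocyanin genes leaned down in epicarp (camera 1.05e-05, alternatives 1.34e-06 to 0.442) and mesocarp (0.0023, alternatives 0.000462 to 0.967). AN11 fell by 1.15 ± 0.18 in epicarp (0.00146) and JAF13 by 1.05 ± 0.15 in mesocarp (0.00161). C4H_06g150137 (Solyc06g150137.1), a cinnamate hydroxylase, fell from 1564 ± 296 to 507.9 ± 203 CPM in epicarp (-1.62 ± 0.23, 0.000699). The pectinesterase gene Solyc01g098940.3 fell from 16.5 ± 4.35 to 0.95 CPM in mesocarp (-4.11 ± 0.61, 0.00271). A pair of thiamine synthesis genes rose in epicarp, Solyc07g064160.3 by 2.34 ± 0.39 (0.00257) and Solyc06g006080.3 by 2.27 ± 0.30 (0.000439).

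Fruit lit for 5 d was compared with light-grown control to learn what still differed after the cover had been off for days. In epicarp a minority of the anthocyanin genes were past the threshold. These fruits were older than the control by the 5 d of light, so age may account for part of any difference. Epicarp had 1652 genes higher and 1278 lower than control (2930 in all, 14.9%). The total was 1407 and 1505 without 5 d replicates 1 and 2, 1511 and 1666 without control replicates 1 and 2, and 5150 with only the groups compared. On TPM 41.5% of the calls were higher, against 56.4% here. Of 15 anthocyanin genes 4 were higher (9 adjusted over the list alone, 8 over all genes with only the groups compared; camera 8.69e-06, alternatives 1.94e-06 to 0.294). The 4 became 1 without 5 d replicate 1 or 2 or control replicate 2 or 3, and 2 without control replicate 1. DFR was higher by 1.05 ± 0.28 (0.0156), a call lost without 5 d replicate 1 (0.112) or 2 (0.0713) or control replicate 2 (0.0593) or 3 (0.0605). OMT (Solyc09g082660.3), a methyltransferase of anthocyanins, was higher by 1.28 ± 0.28 (0.00466), AN11 by 0.87 ± 0.18 (0.00338) and MYB-ATV by 2.57 ± 0.36 (0.000318). F3'5'H overlapped between the groups (888 to 2230 TPM at 5 d, 964 to 1100 TPM in control). It did not pass (0.62, 0.147), though it did without 5 d replicate 3 (1.02, 0.01). ZEP was higher by 1.17 ± 0.19 (0.00061), GLK2 by 2.21 ± 0.47 (0.00444), POR_07g054210 by 1.12 ± 0.22 (0.00234) and SUS3 by 1.62 ± 0.30 (0.00154). BCH1 (Solyc06g036260.3), a carotene hydroxylase, was lower by -1.36 ± 0.30 (0.00518) and FUL2 (Solyc03g114830.3), a MADS-box ripening factor, by -1.09 ± 0.14 (0.000107). Of 5 glycoalkaloid genes 4 were lower, also when adjusted over the list alone (camera 0.000185, alternatives 0.000156 to 0.232), with GAME6 (Solyc07g043500.1) at -3.74 ± 0.63 (0.00089) and GAME1 (Solyc07g043490.1) at -1.75 ± 0.32 (0.00165).

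In mesocarp the lit fruit was compared with a light-grown control that scarcely expresses the pigment pathway. At 5 d 2474 genes were higher and 1513 lower (3987 in all, 20.3%), and the total was 2558 without 5 d replicate 2 and 2657 without both libraries with recovered reads. The balance of directions depends on the scaling, since limma on log2(TPM + 1) called 6022 genes of which 27.4% were higher, against 62.1% here. All 15 tested anthocyanin genes were higher, also when adjusted over the list alone (camera 2.53e-28, alternatives 3.19e-28 to 0.0129). DFR was higher by 10.36 ± 0.41 (4.49e-12), AN1 by 9.67 ± 0.58 (2.21e-09), F3'5'H by 9.11 (3.27e-14), PAL_10g086180 by 6.57 ± 0.68 (2.51e-06) and AN11 by 1.85 ± 0.18 (1.45e-06). AN2-like was higher by 2.31 ± 0.74 (0.0335), and the call was lost when any 1 of the 6 libraries was left out, with 0.055, 0.0823 and 0.0613 for 5 d replicates 1, 2 and 3 and 0.103, 0.0969 and 0.0632 for control replicates 1, 2 and 3. The call was also lost without both recovered libraries and by limma on log2(TPM + 0.1) and on log2(TPM + 1), with or without a filter. Of 26 photosynthesis genes 20 were higher (23 adjusted over the list alone; camera 1.08e-11, alternatives 1.22e-10 to 0.175). CAB5 (Solyc12g006140.2) was higher by 4.16 ± 0.69 (0.000303) and CAB11 (Solyc03g115900.5) by 3.65 ± 0.73 (0.00161). VDE was higher by 2.29 ± 0.29 (2.11e-05), ZEP by 1.70 ± 0.19 (5.15e-06), BBX24 by 1.72 ± 0.25 (6.88e-05) and CAO_06g060310 (Solyc06g060310.3), which makes chlorophyll b, by 2.02 ± 0.38 (0.000968). PHYB2 was lower by -1.91 ± 0.25 (2.96e-05), FUL2 by -1.15 ± 0.14 (8.42e-06) and GAME6 by -3.27 ± 0.62 (0.00111).

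The tissues were compared at each light time to learn whether the contrast between skin and flesh seen in light-grown fruit is present in fruit from the dark. Of 11 cuticle genes, 7, 7 and 9 were higher in epicarp at 0 d, 2 d and 5 d, and as a set they did not pass with an estimated correlation (0.164, 0.235 and 0.216). At 0 d, 1723 genes were higher in epicarp and 1877 lower (3600 in all, 18.3%), and 37 in all with only the groups compared. F3H was higher in dark epicarp by 4.44 ± 0.59 (6.07e-05), A3GT by 4.57 ± 0.53 (1.67e-05), FLS by 4.08 ± 0.69 (0.000512) and MYB12 by 3.19 ± 0.45 (0.000113), and these 4 calls were lost in that fit. DFR did not pass at 0 d (0.84 ± 0.35, 0.104), with overlapping libraries, though it did without mesocarp 0 d replicate 1 (1.26, 0.0294) and with the paired block (0.87, 0.0375). A transporter gene of the pleiotropic drug resistance family (Solyc05g055330.3) was higher by 5.78 ± 0.52 (1.06e-06) in every alternative. Of 11 cuticle genes 7 were higher at 0 d, also when adjusted over the list alone (camera 1.36e-08, alternatives 2.03e-13 to 0.164), and 1 with only the groups compared.

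At 2 d, 1608 genes were higher in epicarp than in mesocarp and 2030 lower (3638 in all, 18.5%). The total was 2279 and 2399 without epicarp 2 d replicates 2 and 3, and 5750 with only the groups compared. On TPM 56.9% of the calls were higher in epicarp, against 44.2% here. Of 15 anthocyanin genes 2 were higher in epicarp (1 adjusted over the list alone, 1 when any 1 of the 6 libraries was left out, 9 with only the groups compared; camera 0.00651, alternatives 7.24e-06 to 0.631), and DFR did not pass (0.50 ± 0.28, 0.23), though it did with the paired block (0.0407) and with only the groups compared (0.0132). F3'H was higher in epicarp by 2.61 ± 0.57 (0.00348), F3'5'H by 1.43 (0.00144), WRKY44 by 3.05 ± 0.70 (0.00497), AN11 by 1.55 ± 0.18 (1.04e-05) and MYB12 by 1.69 ± 0.43 (0.00909). MYB76 (Solyc05g008250.2), a MYB factor, was at 31.47 CPM in epicarp and 4.602 ± 2.78 CPM in mesocarp (2.78 ± 0.56, 0.00193). JAF13 was lower in epicarp by -0.81 ± 0.15 (0.00102), GLK2 by -2.96 ± 0.48 (0.000282) and PRR5 by -2.04 ± 0.40 (0.00131). Of 11 cuticle genes 7 were higher, also when adjusted over the list alone (camera 1.22e-05, alternatives 1.08e-08 to 0.235). CER3 was higher by 7.30 ± 0.72 (1.99e-06), CER6 (Solyc02g085870.3), of wax elongation, by 6.58 ± 0.75 (9.03e-06) and a BURP-domain gene (Solyc08g068150.4) by 8.32 ± 0.76 (9.65e-07). Prosystemin (Solyc05g051750.3), the precursor of a wound peptide, had no reads in epicarp at 2 d and stood at 129 ± 41.7 CPM in mesocarp.

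At 5 d, 1397 genes were higher in epicarp and 2035 lower (3432 in all, 17.5%). The total was 2162 and 2220 without epicarp 5 d replicates 2 and 3, and 2270 without mesocarp 5 d replicate 1. DFR stood at 3049 ± 1080 CPM in epicarp and 2685 ± 782 CPM in mesocarp, with overlapping libraries (0.18 ± 0.27, 0.699). F3'H was higher in epicarp by 3.98 ± 0.61 (0.000182), FLS by 3.72 ± 0.67 (0.000855) and MYB12 by 2.31 ± 0.44 (0.00127). F3'5'H overlapped between the tissues (888 to 2230 TPM in epicarp, 544 to 1260 TPM in mesocarp) and did not pass (0.74, 0.0843). It did pass without epicarp 5 d replicate 3 (1.14, 0.00481) or mesocarp 5 d replicate 2 (0.96, 0.0484). PIF4 (Solyc07g043580.4), a phytochrome-interacting factor, was lower in epicarp by -0.66 ± 0.13 (0.00131), PRR5 by -1.70 ± 0.38 (0.00396) and E8 by -5.07 ± 0.96 (0.00126). CER3 was higher by 7.61 ± 0.70 (1.02e-06), and 9 of 11 cuticle genes were higher (11 adjusted over the list alone; camera 9.41e-08, alternatives 1.06e-13 to 0.216).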

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

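All tests of explanations in this part, and the regroupings of libraries, were chosen only after the results were seen. The results below stand here because the effect in epicarp differed from that in mesocarp in a test of the difference itself. The tissues themselves are a biological difference of the design and stay among the open explanations, untested.

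In the interaction of 0 d with control 503 genes passed, against 1187 by DESeq2 and 1451 with the samples of a number paired as a block. The count was 1348 without epicarp 0 d replicate 1, 307 without epicarp 0 d replicate 2, 318 and 289 without epicarp control replicates 1 and 3, and 322 without mesocarp control replicate 3. The log2 difference was -8.65 for DFR, -7.39 for ANS, -9.33 for 5GT, -9.89 for GST, -9.03 for F3'5'H, -7.83 for AN1, -1.20 for AN11, -5.07 for Solyc11g072830.1, -6.03 for CAB3B and 1.70 for PHYB2. Pigment genes near 0 in mesocarp control, such as F3'5'H at 0.6933 TPM, could hardly fall further in mesocarp. Their differences do not show a weaker response of the flesh. CAB3B and PHYB2 did not pass with only the groups compared. In that model 58 genes passed, and 4 of 100 splits of the libraries gave as many, with 776 as the highest of the others. All 4 were among the 10 splits that kept the controls whole, and the other 90 gave at most 1, since mixing tissues within the controls puts the tissue difference into the spread. These splits therefore do not decide whether chance is excluded.

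In the interaction of 2 d with 0 d 244 genes passed, against 930 with the samples of a number paired as a block, a pairing of which the splits take no account. The count was 469 and 438 without epicarp 0 d replicates 1 and 3, 158, 120 and 129 without epicarp 2 d replicates 1, 2 and 3, and 151 without mesocarp 2 d replicate 1. The log2 difference was 1.38 for AN11, -4.13 for F3H, -4.24 for A3GT, -2.82 for PAL_09g007900 and -7.71 for Solyc05g009500.3, and the last 4 did not pass with only the groups compared. In that model 47 genes passed, 3 of 100 splits gave as many, with 195 as the highest of the others. All 3 were among the 10 that kept the 2 d libraries whole, so chance is not excluded here either.

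In the interaction of 5 d with 0 d 38 genes passed, among them A3GT at -4.01, against 258 with the paired block, of which the splits take no account. The count was 115 and 69 without epicarp 0 d replicates 1 and 3, 10 without epicarp 5 d replicate 1 or 2, 24 and 101 without mesocarp 0 d replicates 2 and 3, and 13, 14 and 20 without mesocarp 5 d replicates 1, 2 and 3. The call for A3GT was lost without epicarp 5 d replicate 1 (0.0552) or 2 (0.0788), mesocarp 0 d replicate 2 (0.0608), or mesocarp 5 d replicate 1 (0.0572) or 2 (0.0585). With only the groups compared 1 gene passed, 2 of 100 splits gave as many, with 4 as the highest of the others, and both were among the 10 that kept the 5 d libraries whole, so chance is not excluded. In each of these interactions the highest split put epicarp 0 d replicates 2 and 3 together with mesocarp 0 d replicate 3. Such a split mixes the tissues only at 0 d and keeps the other condition whole. Its contrast therefore holds the tissue difference of that condition, which alone can give more genes than the real split. These high counts thus do not show a structure of the 0 d libraries.

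The 0 d libraries differed in ripening and cuticle genes. A difference in depth is excluded, since the median ratio of the highest to the lowest epicarp library over these genes was 17.1 and the ratio of total reads 1.14. A 0 d label on a lit epicarp sample or a 2 d or 5 d mesocarp sample is excluded, since DFR reached at most 1.36 CPM at 0 d and at least 1340 CPM in those libraries, and such a label on a light-grown mesocarp sample is excluded by principal components 1 to 4, where each 0 d library lay at least 64.4 from the mean of the mesocarp controls and these at most 20.3 from each other's mean, while a sample from outside the study stays open. A batch of sampling or preparation shared by the samples of a number cannot be told apart from fruits that differ in stage, since epicarp and mesocarp of the same number deviated together by at least 0.39, against at most -0.11 for other numbers, which either would give. In mesocarp 0 d replicate 1 each of 10 cuticle genes reached at least 0.056 of its level in the epicarp library of that number, against a lowest share of at most 0.0094 in the other mesocarp libraries, so carried-over skin may account for its cuticle transcripts, though not for the differences among the epicarp libraries.

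Anthocyanin genes were high in mesocarp after light. Epicarp carried into the mesocarp samples is excluded as the source at 2 d, because the highest of 6 cuticle genes reached 0.18 of its epicarp level in mesocarp and the lowest pigment gene other than F3'H 0.39. F3'H stood at a share of 0.163, under that of CD2. Against carried skin as its source, 3 of the 6 cuticle genes lay over 10-fold lower (CER3 0.00648, CER6 0.0105, TTS1 0.0121). The median of the 6 was 0.045, and the same limit of this test holds. Scaling is excluded, with 15 of 15 genes higher at 2 d under RLE scaling and on TPM, as are reads of overlapping genes, with 13 of 13 genes that no other gene overlaps. A response of the flesh itself to light, to removal of the cover or to age may be the source. This hypothesis was found and tested on the same data.

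Photosynthesis genes were lower in dark epicarp, with 15 of 26 showing a lower epicarp than mesocarp effect. The 0 d libraries numbered 3 are excluded as the whole cause, with 16 genes without them, and scaling is excluded, with at least 15 genes under RLE scaling and on TPM. The count was 8 without mesocarp control replicate 3, and with only the groups compared edgeR called 0 (21 at an unadjusted p under 0.05), against 21 by DESeq2 and 18 by limma on TPM. As a set they passed by camera (7.11e-21, alternatives 4.92e-21 to 0.151) and not with an estimated correlation. The 0 d batch named above stays open, so no biological reading is given.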

How the results depend on the processing

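The fits without the 0 d libraries numbered 3 and without the 2 recovered libraries are tests chosen only after the results were seen; the other alternatives were chosen before the data were examined. No tissue correlation or named gene reversed under any of them. Of 193 pairs of a named gene and a contrast, 182 passed the threshold, and 159 of these passed under every setting run for them. Among 3100 values compared, 44 fell below the threshold, 15 rose past it and 0 reversed. Counts below are genes past the threshold. Unless a cause is given, the cause was not tested.

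A minimum fold of 2 asks for more by construction and gave 1829 genes in epicarp at 0 d against control and 348 in mesocarp, 4113 and 2328 at 2 d against 0 d, 2979 and 1716 at 5 d against 0 d, 303 and 192 at 5 d against 2 d, and 1354 and 2078 at 5 d against control. Between tissues it gave 3171 in control, 2041 at 0 d, 2237 at 2 d and 2131 at 5 d.

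A model of only the groups compared estimates the spread from fewer libraries. It gave 898 genes in epicarp at 0 d against control and 6 in mesocarp (0.7% of the genes of the full model were called again). It gave 2146 in mesocarp at 2 d against 0 d (44.1%), 2790 in epicarp (48.6%) and 802 in mesocarp (20.9%) at 5 d against 0 d, and 37 between tissues at 0 d (1.0%). Where the 0 d libraries were not involved it gave more: 2406 in epicarp at 5 d against 2 d, 5150 at 5 d against control and 5750 between tissues at 2 d. Fewer libraries alone therefore cannot account for the lower counts with 0 d. Replicates correlated by 0.8712 to 0.9369 at 0 d and by 0.9517 to 0.9847 in the other groups. The spread shared by all groups may thus be too small for 0 d, and p-values there too low. The interactions fell to 58, 47 and 1 (0 d against control, 2 d and 5 d against 0 d; 11.3%, 18.4% and 2.6%). The correlations of the effects in both tissues were 0.47, 0.79 and 0.79.

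DESeq2 gave 1742 genes in mesocarp at 0 d against control, 1348 in epicarp and 1104 in mesocarp at 5 d against 2 d, and 1187, 762 and 280 for the interactions. On log2(TPM + 1) limma gave 1419 in mesocarp at 0 d against control, 6022 in mesocarp at 5 d against control, 926, 404 and 81 for the interactions, and correlations of 0.78 at 2 d and 0.78 at 5 d. Without its filter these were 1482, 5995, 953, 407, 79, 0.77 and 0.78. On log2(TPM + 0.1) the interaction at 5 d was 61 and the correlations 0.71 and 0.71. With no low-count filter the interaction at 5 d was 23 and the correlations were 0.32, 0.49 and 0.47, since more genes near 0 reads entered. The stricter filter gave 0.70 at 2 d.

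The TPM values are not scaled by TMM. On log2(TPM + 1) the median log2 change of all genes was -0.21 in mesocarp at 5 d against control (0 from counts), -0.18 in mesocarp at 2 d against 0 d (-0.05), -0.09 in mesocarp at 0 d against control (0.01), -0.11 between tissues in control (0.01) and 0.15 in the interaction of 0 d with control (0.02). The share of called genes that were higher also moved. In mesocarp it went from 55.8% to 20.5% at 0 d against control, from 55.2% to 36.3% at 2 d and 57.9% to 40.7% at 5 d against 0 d, and from 62.1% to 27.4% at 5 d against control. In epicarp at 5 d against control it went from 56.4% to 41.5%, between tissues from 49.3% to 36.0% in control and from 44.2% to 56.9% at 2 d, and in the interactions from 29.0% to 56.9%, 53.7% to 74.8% and 44.7% to 58.0%. On log2(TPM + 0.1) it also went from 42.5% to 55.1% in mesocarp at 5 d against 2 d.

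With the epicarp and mesocarp samples of a number paired as a replicate block, the interactions held 1451, 930 and 258 genes. Control numbers did not pair, so the 1451 rests partly on numbers alone. Within a tissue the block was instead the replicate number across conditions. Of 156 list tests past the threshold by camera, 22 passed with an estimated correlation, and 136 by fry and 174 with these blocks were past it. The block within a tissue brought past the threshold AN2-like in epicarp at 0 d against control (-2.20, 0.0407). Same-number correlations between these groups were only 0.14, 0.1 and 0, so this call rests on numbers alone. The paired block brought past the threshold DFR between tissues at 0 d and 2 d. Neither block changed another named call or moved another contrast count by over 1.5 times.

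Without the 2 recovered libraries mesocarp held 2473 genes at 5 d against 0 d, 121 at 5 d against 2 d and 2657 at 5 d against control, and the interactions 155 at 2 d and 13 at 5 d; fewer libraries are part of the cause. Without the 0 d libraries numbered 3 the interactions held 490 at 2 d and 109 at 5 d, and the correlations were 0.29 for 0 d against control and 0.62 at 2 d.

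Leaving out each library in turn gave 2210 to 5138 genes in epicarp and 408 to 1938 in mesocarp at 0 d against control, 5516 to 7238 and 3565 to 4585 at 2 d against 0 d, and 4076 to 5561 and 2347 to 3751 at 5 d against 0 d. It gave 198 to 452 and 162 to 386 at 5 d against 2 d, and 1407 to 2755 and 2558 to 3353 at 5 d against control. Between tissues it gave 3949 to 4476 in control, 2637 to 3750 at 0 d, 2279 to 2815 at 2 d and 2162 to 2667 at 5 d. The interactions ran from 289 to 1348, 120 to 469 and 10 to 115, and the correlations from 0.28 to 0.42, 0.57 to 0.65 and 0.53 to 0.65. Depth limits genes near 3 reads, while the spread between replicates limits the rest.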

Other observations

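The comparisons of 10 splits in this part are tests chosen only after the results were seen; the list tests were fixed before the data were examined. Lists not described above were followed in epicarp at 2 d of light against 0 d. Of 16 carotenoid genes 7 rose and 1 fell, also when adjusted over the list alone (camera 0.00462, alternatives 6.7e-06 to 0.266). Of 12 chlorophyll and chloroplast genes 6 rose and 1 fell, with the same counts over the list alone (camera 0.00324, alternatives 0.000708 to 0.388). Of 7 genes of photoprotection and ascorbate 4 rose and 1 fell, again the same (camera 0.0993, alternatives 9.66e-06 to 0.269). Of 24 light-signalling genes 7 rose and 6 fell (8 and 6 adjusted over the list alone; camera 0.477, alternatives 0.132 to 0.735). Of 9 clock genes 3 fell, also over the list alone (camera 0.44, alternatives 0.00668 to 0.569). Of 10 genes of sugar and starch 3 rose and 1 fell (3 and 2 over the list alone; camera 0.477, alternatives 0.0168 to 0.569).

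Among lists drawn from descriptions, histones and cell division had 40 of 129 genes higher and 11 lower in epicarp at 2 d than at 0 d (41 and 11 adjusted over the list alone; camera 0.00283, alternatives 0.00305 to 0.529). Cell wall loosening had 4 of 35 higher and 14 lower (4 and 15 over the list alone; camera 0.129, alternatives 0.00859 to 0.388). Auxin response had 3 of 24 higher and 5 lower (4 and 5; camera 0.772, alternatives 0.637 to 0.78). Wound and proteinase inhibitor genes had 6 of 28 higher and 5 lower (6 and 5; camera 0.44, alternatives 0.0266 to 0.569), and pathogenesis-related genes 5 of 48 higher and 2 lower (5 and 2; camera 0.477, alternatives 0.0454 to 0.683). Cutin and wax had 6 of 112 higher and 19 lower (6 and 11; camera 0.477, alternatives 0.458 to 0.815), where the 19 became 7 without 0 d replicate 1 and 9, 7 and 9 without 2 d replicates 1, 2 and 3.

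Of 89 seed genes 4 were higher and 29 lower in epicarp than in mesocarp of control fruit (4 and 31 adjusted over the list alone; camera 0.00038, alternatives 8.71e-05 to 0.123), and the 29 became 15 and 17 without epicarp control replicates 2 and 3. In mesocarp at 5 d against control, 8 of 16 carotenoid genes were higher (9 over the list alone; camera 2.47e-05, alternatives 1.02e-06 to 0.0414), as were 8 of 12 chlorophyll and chloroplast genes (9 over the list alone; camera 1.43e-06, alternatives 2.93e-06 to 0.113). At 0 d the epicarp replicates 1, 2 and 3 stood at 4561, 930 and 449 CPM for SUS1, a sucrose synthase, at 210, 36.9 and 30.2 CPM for the clock gene LHY, and at 0.05, 2.36 and 32.4 CPM for ACS2, of ethylene synthesis.

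For contrasts of 3 libraries with 3 there are 10 splits, too few for a share under 0.05, and in each contrast only the real split, 1 of 10, gave as many genes, with 0 as the highest of the others. Every other split mixes libraries of both groups and so puts a real difference into the spread. Low counts are thus built into those splits, and they do not decide whether chance is excluded. With only the groups compared, edgeR's real values were 898 in epicarp and 6 in mesocarp at 0 d against control, 4899 and 2146 at 2 d against 0 d, 2790 and 802 at 5 d against 0 d, 2406 and 529 at 5 d against 2 d, and 5150 and 4290 at 5 d against control. Between tissues they were 6369 in control, 37 at 0 d, 5750 at 2 d and 3660 at 5 d.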
